A study of Drosophila melanogaster with 2 samples.

How the data were processed

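Binding of GFP-tagged mod(mdg4) was measured by chromatin immunoprecipitation with an anti-GFP antibody and sequencing, in whole larvae of a single line. Per the labels, chromatin was sheared by sonication to fragments of 200 to 800 bp, and the 2 biological replicates are numbered 3 and 4. They form 1 group, and no technical batch is given in the labels.

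The authors processed the same libraries on dm3 and dm6. For each build, the deposited lists hold peaks and background called on each replicate alone and on the pooled reads of both replicates against a control library, and a series-wide list of peaks that passed the optimal IDR threshold, made from those lists. The peak caller, the IDR threshold and the treatment of reads that match several places are not given in the sources used here. The control library itself was not used here. All lists have the narrowPeak layout without a header. The signal of each peak is, as deposited by the authors, the peak caller's strength of enrichment over the control library, and its scale depends on the list, so signals were compared within a list, with 2 exceptions. Replicate signals were compared by rank and after scaling to their medians, and the dm3 and dm6 lists of the same reads by their raw signals, with the ratio of nuclear medians given as a check of the scales. The -log10 q of each peak is the authors' own significance value as deposited; it reaches a ceiling of 2.46 in 43.9% of the thresholded dm6 peaks and was used only to describe the lists. The deposited summit offset gives the position of the summit from the start of the peak in bp, and all peaks were placed by their summits. Most peaks of the thresholded list (78.6%) have a width of 416 bp, so widths were not analysed. Of the 6294 thresholded dm6 peaks, 6293 have an interval and summit of the pooled list and rank among its strongest 6294. Both replicate lists and the pooled list hold 29999 peaks on dm6.

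The lists give no read counts, so sequencing depth is unknown, and no interval that needs it is given. Intervals on shares of peaks or genes are exact 95% binomial intervals and cover the number of peaks or genes only, not differences between animals.

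Coordinates are those of dm6, counted from 1. Genes and transcripts were taken from Ensembl release 115 for the same assembly, and dm3 lists were compared by count, signal and arm only, without conversion of coordinates. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, with matplotlib 3.10.9 for figures. A promoter peak has its summit within 500 bp of any start site of a protein-coding gene, and all other peaks are called distal. Where a summit lay in several annotated features, coding exons took precedence over UTRs, noncoding exons and introns.

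The following comparisons, lists, motifs and regions were fixed before the data were examined. Overlap of the strongest 6294 peaks of each replicate was tested by one-sided permutation against 1000 circular shifts within chromosomes. The share of promoter summits was tested by permutation against 1000 random placements on the same arms that avoided unknown bases. The permutation p of this share is that of the smaller tail, not doubled. Signal at promoter and distal peaks was compared by the difference of medians with a two-sided permutation test of 100000 resamples. For 20 gene lists (13945 protein-coding genes on the arms), two-sided Fisher exact tests compared members with all other genes. For 14 motifs, windows reaching 100 bp to each side of a summit were compared with paired windows centred 1000 bp away, on a side drawn at random, by two-sided exact McNemar tests, and each motif read backwards served as a control. The same motifs were compared between promoters with and without a peak at the outermost start site of each gene by two-sided Fisher exact tests. The X share of peaks on the 5 largest arms was compared with that of start sites, merged within 500 bp, by a two-sided exact binomial test. Benjamini-Hochberg adjustment was made within each family, with a threshold of 0.05. Intervals on rank correlations, median differences and ratios come from 1000 bootstrap draws of peaks. Symbols of the gene lists that the annotation lacks were matched through unambiguous synonyms, and those without a match were left out.

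Genes are named by 3 rules. The first takes the gene whose start is nearest to each of the 25 strongest thresholded peaks, where it is within 500 bp. The second takes up to 4 members of each list with the strongest promoter peaks and up to 2 members without one, in alphabetical order. The third takes mod(mdg4) and the genes that bound the 5 regions. Genes named beyond these rules were chosen after their values were seen. In the report these are further ecdysone and heat shock genes, Trl, BEAF-32, Cp190, the strongest arm peaks and the neighbours of mod(mdg4). They also include the second gene of a peak shared at equal signal and genes with a start nearer to a list member's peak. Others are the genes in or beside which peaks of the named regions and the mitochondrial genome lay. In the closing section they are all genes not named before.

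Each comparison with a test was run on simulated data, with motifs on fewer windows and promoters than in the real data; the rank correlation was not tested in this way. For the overlap of 6000 peaks of which 60% were planted as shared, 61.6% was recovered. For the promoter share, 38.05% was planted and 38.03% recovered. For gene lists over 13945 genes, all changed lists (100%) and 2% of unchanged lists were called. For motifs planted in 5% of 1000 windows, 5% was recovered, and in 50% of 1000 promoters, 50%. For an X share of 20% against 17% over 6000 peaks, 100% of runs were called. For the signal of 6000 peaks, with 1000 resamples in place of 100000, promoter signal planted 1.2 times higher gave a permutation p of 0.001, the smallest that these can give, and with none planted the permutation p was 0.0989.

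The alternatives tried were promoter distances of 250 and 1000 bp, start sites of all gene types, genes with 1 start site, members within 2 kb counted once, windows of 50 and 200 bp to each side, control windows 2000 bp away, the stronger 3147 peaks, the strongest 12588 pooled peaks, other overlap rules, dm3 lists, arm length as reference for X, and each replicate alone. Alternatives added after the data were seen were nuclear chromosomes only, histone genes left out, only peaks strong in both replicates, and the 25 strongest peaks on the arms. Peaks strong in both replicates are the 4459 thresholded peaks that overlapped a peak among the strongest 6294 of each replicate. Mitochondrial peaks were left out of all comparisons with genes and motifs, because the random placements and control windows are defined on the arms.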

Results

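Chromatin immunoprecipitation with sequencing was used to locate mod(mdg4), a BTB-domain protein best known as a partner of su(Hw) and other insulator proteins, in Drosophila melanogaster. The animals were wandering larvae of the third instar, males and females pooled, from a transgenic line that carries mod(mdg4) with a C-terminal GFP, and the precipitation used an antibody against GFP. The peaks are therefore those of protein with this tag, and forms of mod(mdg4) without it were not measured. There was 1 group with 2 biological replicates, numbered 3 and 4, so the only comparison between samples is between these replicates. All other comparisons are made within the list of peaks that passed the irreproducible discovery rate (IDR) procedure, which holds 6294 peaks on dm6. Of these, 6273 lay on the 6 chromosome arms and 21 on the mitochondrial genome. The number of reads per sample is unknown, because the lists give a signal per peak and no counts. Peak signal is the peak caller's own value on a scale of its list, so signals are compared within a list, except between the replicates and between the builds, where this is said. Signals given for single peaks come from the pooled list, so they have no replicate error of their own.

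The question of the first comparison was how far the replicates gave the same peaks. The strongest arm peaks stood near the top of both replicate lists, behind mitochondrial peaks, which are counted in the places given here. The peak at the start of Ugalt, which encodes a Golgi transporter of nucleotide sugars, held place 25 in each replicate list. The peak at su(Hw), the gene of the zinc-finger protein that recruits mod(mdg4) to insulators, held places 37 and 47, and that at Hsp27, a small heat shock protein gene, held places 43 and 182. Among the 6294 strongest peaks of replicate 3, 73.3% overlapped a peak among the 6294 strongest of replicate 4 by at least 1 bp. Circular shifts of the replicate 4 peaks along each chromosome gave a mean of 3.70% and a highest value of 4.61% (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). In the other direction the overlap was 71.7%. Of the 6294 thresholded peaks, 4459 (70.8%) overlapped a peak among the strongest 6294 of each replicate, 1690 did so in a single replicate and 145 in neither. In the full replicate lists, 6217 (98.8%) overlapped a peak of both.

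Across these 6217 peaks, Spearman's rho between the replicate signals was 0.653 (bootstrap 95% interval 0.635 to 0.669), where peaks are not independent replicates. After scaling each replicate to its median, 89.9% of the peaks were within 2-fold of each other, and the SD of the log2 ratio was 0.61. Among the 3098 of these peaks in the weaker 0.5 of the list, which span a narrow band of pooled signal by their selection, rho was -0.105, and among the 3119 stronger ones it was 0.657.

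**Figure D1:**
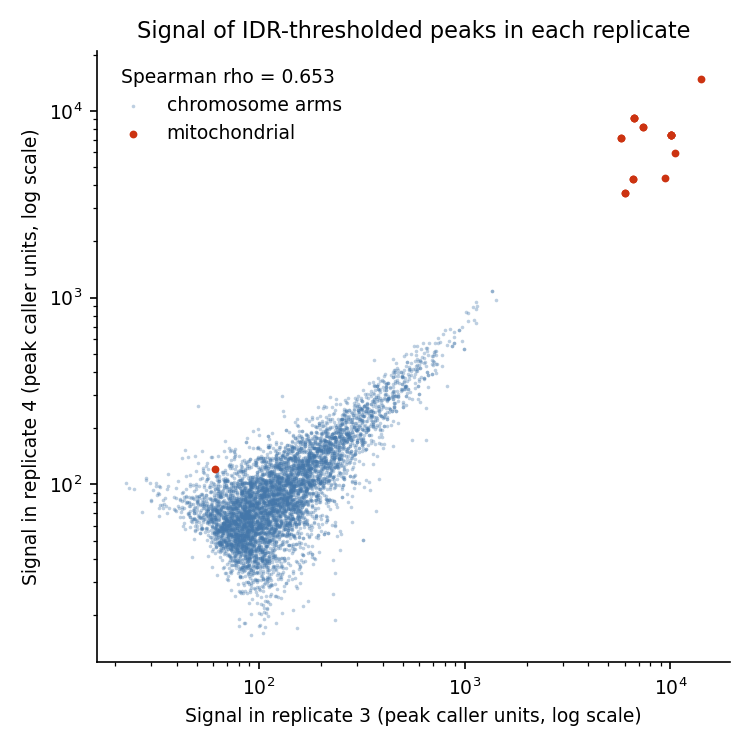
Signal of each thresholded peak in replicate 3 (x axis) and replicate 4 (y axis), both in peak caller units on log scales, with 1 point per peak on the chromosome arms (blue) or the mitochondrial genome (red). Spearman's rho over all 6217 peaks found in both replicate lists was 0.653, and the mitochondrial points lie above the arm points except for a single one.

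Summits were concentrated near gene starts, and few lay in coding exons. Of the 6273 arm peaks, 2637 (42.0%) had their summit within 500 bp of the start site of a protein-coding gene. Randomly placed summits on the same arms gave 11.5% (SD 0.406 over 1000 placements). The share at peaks was thus 3.67 times higher (permutation p = 0.001 in the smaller tail, the smallest that 1000 placements can give). The 6294 strongest peaks of each replicate gave 44.5% ± 1.71 (SD, n = 2). The distance from a summit to the nearest start site had quartiles of 167 bp (lower) and 3296 bp (upper).

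Introns held 47.9% of the summits against 39.9% of random positions, and sequence between genes held 37.8% against 27.5%. The 5' UTRs held 7.30% against 3.02%. Coding exons held only 36 summits, or 0.574% (exact 95% interval 0.402 to 0.794), against 17% of random positions. The 3' UTRs (3.57% against 4.99%) and noncoding exons (2.89% against 7.60%) held fewer summits than random positions did. These classes were described without a test. Density per Mb varied little between arms, from 44.7 peaks on 2R to 50.3 on chromosome 4, which held 67 peaks. Per 100 protein-coding start sites, merged within 500 bp, it varied more, from 36.7 on 2R to 60.4 on chromosome 4.

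Promoter peaks were stronger than distal ones. Their median signal was 199 against 176 for the 3636 distal peaks, a difference of 22.8 (bootstrap 95% interval 17.2 to 28.6; two-sided permutation p = 1e-05, the smallest that 100000 resamples can give). In the lists of single replicates, which have lower signal scales, the difference was 14.04 in replicate 3 and 7.01 in replicate 4. On the pooled scale it was 14.01 among the stronger 3147 peaks (permutation p = 0.0087) and 37.9 among the strongest 12588 pooled peaks.

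Among named genes, the peaks at ecdysone response, heat shock and ribosomal protein genes were more frequent than at other genes, while those at larval cuticle, odorant and gustatory receptor and histone genes were less frequent. A promoter peak was present at 2613 of 13945 protein-coding genes (18.7%). The 20 lists were compared with all other protein-coding genes by two-sided Fisher exact tests with Benjamini-Hochberg adjustment over the lists. The lists gave 3 calls above other genes, 3 calls below and 14 without a call.

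Of the 24 ecdysone response genes, which carry the steroid signal for moulting and pupariation, 15 (62.5%) had a promoter peak (odds ratio 7.26, exact adjusted p = 1.86e-05), and 14 of 24 did in each replicate. The ecdysone receptor genes usp and EcR carried signals of 619.2 (X 2042249–2042598) and 580.3 (2R 6131846–6132261, in an EcR intron 132 bp from a start site). The zinc-finger gene br, a primary target of the hormone, had 341.1 and the lactate dehydrogenase gene Ldh 337.8. Other members with a peak were the early genes Eip75B (295.0) and Eip74EF (254.9) and the nuclear receptor genes Hr78 (273.5), ftz-f1 (210.6), Hr4 (193.4) and Hr3 (151.4). Blimp-1 and Cth had none. The call rested on genes with several start sites: among the 6 members with 1 annotated start site, 1 (16.7%) had a peak, against 12.96% of other such genes (exact adjusted p = 0.942).

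Of 23 heat shock genes, 11 (47.8%) had a promoter peak (odds ratio 3.99, exact adjusted p = 0.0048), with 13 in replicate 3 and 11 in replicate 4. The small heat shock protein gene Hsp27 had 1161.4 (3L 9383725–9384069, 161 bp from its start). The chaperone genes Hsc70-4 (400.9), Hsp83 (382.5) and Hsp110 (365.9) followed. Neighbours of Hsp27 in the same cluster, Hsp23 (273.7), Hsp26 (266.6) and Hsp22 (225.0), also had peaks. CG4456 and Hsc70-5 had none, and neither did any of the 6 Hsp70 genes on 3R, which are near-identical copies. With 1 annotated start site only, 4 of 13 members (30.8%) had a peak against 12.9% of other such genes, which was not a call (exact adjusted p = 0.198).

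Of 92 ribosomal protein genes, 36 (39.1%) had a promoter peak (odds ratio 2.81, exact adjusted p = 2.54e-05), with 39 in replicate 3 and 44 in replicate 4. RpS13 had 867.9 (2L 8364572–8364942), RpL30 had 579.9 and RpS21 510.9. The start nearest to the RpS13 summit was that of CSN8, and the start nearest to the RpS21 summit that of CG3104. RpL13 shared a peak of 828.3 (2L 9967079–9967414) with Dref, which lies in the opposite direction and encodes the factor that binds the DNA replication-related element (DRE). RpL10 and RpL10Aa had none.

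Only 4 of 96 genes of the larval cuticle list (4.17%, odds ratio 0.187, exact adjusted p = 2.25e-04) had a promoter peak. Lcp2 and Lcp3 shared 1 of 551.6 between them (2R 8435010–8435244), Cpr62Ba had 541.6 and Cpr72Eb 131.6. Acp1 and Ccp84Aa had none. The list was drawn up by gene symbol, and expression of its members in larvae was not checked. Among 179 odorant and gustatory receptor genes there were 3 (1.68%, odds ratio 0.0729, exact adjusted p = 2.50e-11), namely Gr64a (206.2), Ir60e (151.5) and Gr97a (123.8). The count was 2 (1.12%) in replicate 3 and 1 (0.559%) in replicate 4. None of the 111 replication-dependent histone genes had a promoter peak (exact adjusted p = 1.37e-09). Those genes are copies of a repeat in a single cluster on 2L, and when clustered genes were counted once the histone call ended (exact adjusted p = 1). How reads that match several copies were treated is not given in the sources used here.

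Just short of the threshold were insulator and architectural protein genes (10 of 27, 37.0%), cell cycle and replication genes (12 of 35, 34.3%) and proteasome genes (3 of 48, 6.25%), each with an exact adjusted p of 0.0614. In the first list, su(Hw) carried 1458.6 in its 5' UTR (3R 14307912–14308347, gene FBgn0003567), Chro, which encodes the chromodomain protein Chromator, 1073.6 (3L 22878731–22879311), Dref 828.3 and jigr1 618.7. Trl, the gene of GAGA factor, had 298.4 and BEAF-32 had 262.5. CTCF, Cap-H2, Cp190 and mod(mdg4) itself had no promoter peak. In the cell cycle list, the APC/C activator gene fzr had 455.4, the transcription factor genes E2f1 and Dp had 395.1 and 306.9, and the cyclin gene CycB3 had 286.1, while Cdk2 and Cdk4 had none. In each replicate list 13 of the 35 cell cycle genes (37.1%) had a peak, which passed the threshold in replicate 3 (exact adjusted p = 0.0471) and not in replicate 4 (exact adjusted p = 0.0798). The strongest proteasome gene was Rpn13, with 1213.5 (2R 13960335–13960728), followed by Rpn6 (375.9) and Prosbeta6 (146.4). Of the 48 proteasome genes, 4 (8.33%) had a peak in replicate 3 and 6 (12.5%) in replicate 4.

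The remaining 11 lists were not called. A promoter peak was present at 8 of 29 Polycomb and trithorax group genes, with ph-p (959.0), Kdm2 (687.4), trx (398.9) and ph-d (265.2) in front, and absent from Asx and E(z). There were 8 of 32 developmental signalling and patterning genes, led by Dll (495.9), ey (285.0), hry (279.0) and sd (212.1), with none at Kr and Ser. There were 4 of 16 apoptosis genes, namely egr (415.9), Cyt-c-d (399.8), Diap1 (308.5) and hid (212.2), with none at Buffy and Cyt-c-p. In replicates 3 and 4 the counts were 5 and 7 for apoptosis genes and 9 and 12 for Polycomb and trithorax group genes. For oxidative phosphorylation the count was 14 of 90, with 21 in replicate 3 and 18 in replicate 4. It was led by the complex I subunit gene ND-B17 (1228.5, 2L 15750985–15751354), COX5A (331.2), COX5B (317.9) and ND-SGDH (290.8), with none at ATPsynB and ATPsynC. The start nearest to the COX5A summit was that of glo, and the start nearest to the COX5B summit that of IFT52. For digestive proteases and lipases it was 9 of 43, with Jon74E (433.8), Mal-A5 (399.6), etaTry (232.8) and, with a shared peak, LManI and LManII (203.8) in front, and none at Amy-d and Amy-p. Among Hox and homeotic complex genes 1 of 12 had a promoter peak, bcd (228.1), and Abd-B and Antp had none. Each of 3 lists had a single gene with a peak: Sgs5 (223.9) among 17 salivary glue and larval serum protein genes, AttD (161.3) among 14 antimicrobial peptide genes, and Mst87F (119.2) among 23 testis-specific genes. Neuronal genes had 2 of 21, elav (528.2) and Syx1A (169.4), with none at ChAT and Ddc, and muscle genes had 2 of 20, Mef2 (172.4) and how (138.0), with none at Act57B and Act79B.

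**Figure D2:**
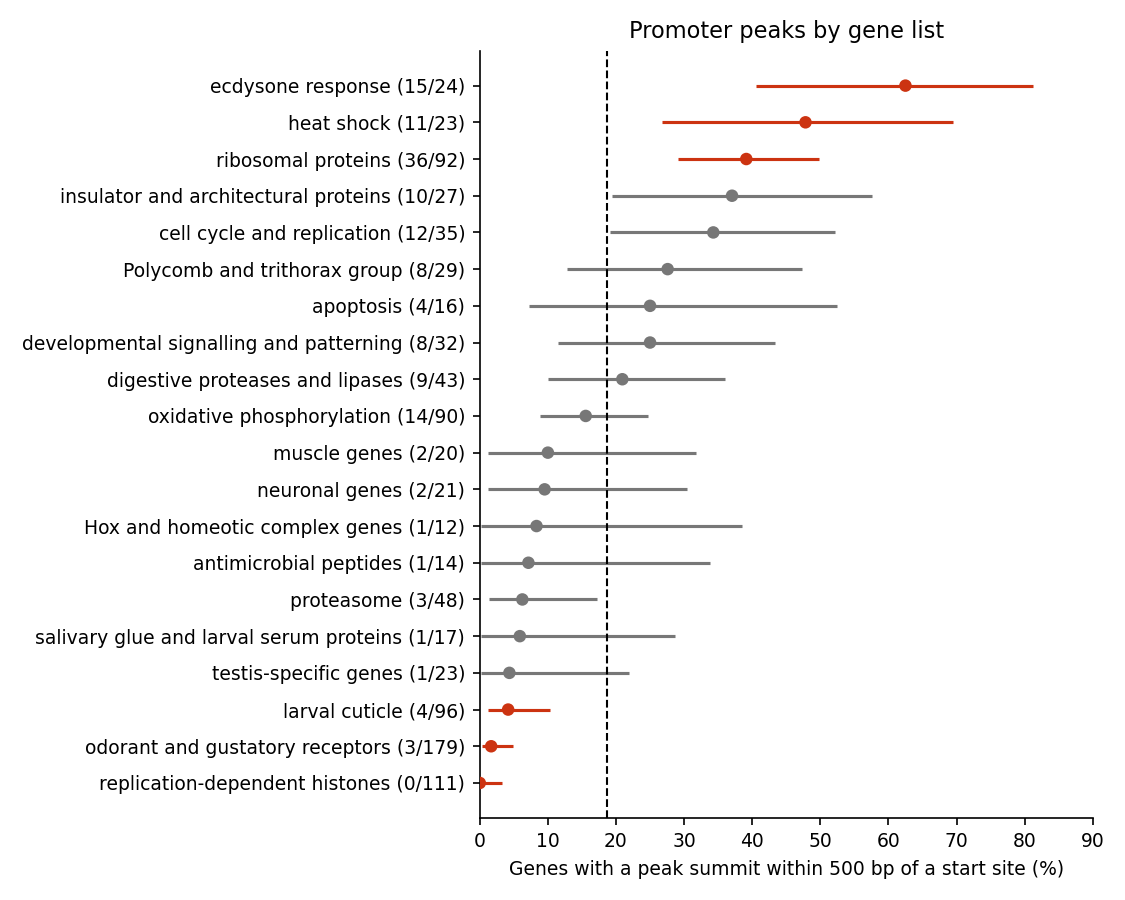
Percentage of the protein-coding genes in each list that had a peak summit within 500 bp of a start site (x axis, %), with exact 95% binomial intervals as bars, counts beside the names, and called lists in red. The dashed line marks all protein-coding genes at 18.7%; ecdysone response genes lie at 62.5% and odorant and gustatory receptors at 1.68%.

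Of the 25 strongest thresholded peaks, 18 were mitochondrial and only 2 lay within 500 bp of the start of a protein-coding gene. These were Ugalt (signal 1999.0, X 2703720–2704073, 45 bp from the start) and CG14100 (1859.8, 3L 19590451–19590840, 90 bp). Among the 25 strongest peaks on the arms, a set chosen after the data were seen, 9 lay within 500 bp of a start. The genes added were CG32301 (1844.8), pyd (1660.1), CG18549 (1525.3), Shrm (1466.3), su(Hw) (1458.6), Lac (1444.5) and CG1888 (1426.9). Introns held 10 of the 25 summits and sequence between genes 11. All 25 were among the first 46 places of replicate 3 and the first 56 of replicate 4, mitochondrial peaks counted.

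Sequences bound by insulator proteins and sequences of housekeeping promoters were more frequent under the peaks than beside them. The su(Hw) site was present in 3.06% of the 6273 windows that reach 100 bp to each side of a summit and in 0.399% of the paired windows 1000 bp away, a ratio of 7.68 (exact adjusted p = 2.46e-32). The core of the CTCF site, another insulator protein's sequence, gave 2.65% against 0.494% (ratio 5.35, exact adjusted p = 4.08e-23). The DRE gave 3.11% against 0.574% (ratio 5.42, exact adjusted p = 9.22e-27), and Motif 1, a promoter sequence bound by M1BP, 1.29% against 0.112% (ratio 11.6, exact adjusted p = 1.25e-16). Smaller ratios were found for Motif 6 (0.925% against 0.287%), the su(Hw) core (7.70% against 4.03%), the GAGA sequence (7.38% against 4.40%), the TATA box (4.88% against 2.98%) and the BEAF-32 element (28.7% against 22.8%), each with an exact adjusted p of at most 7.33e-06. In each replicate's own list the su(Hw) site was at 2.96% and 2.85% of the peaks and the DRE at 3.11% and 4.18%. Because 42.0% of summits lay within 500 bp of a start site, these ratios partly compare promoters with sequence beside them. At distal peaks, split off after the data were seen, the DRE (0.578% against 0.578%) had no excess over control. Neither did the BEAF-32 element (23.0% against 23.2%) or Motif 6 (0.330% against 0.385%). The su(Hw) site kept 4.18% against 0.41% there, and the CTCF core 2.92% against 0.495%.

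Of the 14 motifs, 9 were more frequent at peaks, 1 less frequent and 4 not called by two-sided exact McNemar tests with Benjamini-Hochberg adjustment. Every DRE match also holds the BEAF-32 element, and every su(Hw) site holds the su(Hw) core. These pairs are therefore not separate findings, here or at promoters. The core bound by Pho, a Polycomb recruiter, was less frequent (8.59% against 9.74%, exact adjusted p = 0.0417). That call ended with windows of 50 bp to each side (exact adjusted p = 0.184) and among the stronger 3147 peaks (exact adjusted p = 0.79). It also ended among peaks strong in both replicates, within the strongest 6294 of each (exact adjusted p = 0.859). The E-box (9.58% against 9.20%), the AP-1 site (1.82% against 1.94%), the Zelda site (0.893% against 1.1%) and the EcR site (3 windows in each set) were not called. Without replicate 3, the E-box was called, at 10.6% of the peaks of replicate 4 (exact adjusted p = 0.0045), and with control windows 2000 bp away the Zelda site was called below control (exact adjusted p = 0.0046). Peak windows were poorer in G and C than control windows (37.4% against 42.0%). Each motif read backwards served as a control for composition: the TATA box read backwards was also more frequent at peaks (8.11% against 5.17%, exact adjusted p = 3.11e-10), and the GAGA string reads the same both ways, so it has no such control. The su(Hw) site read backwards was rare, in 9 peak windows and 1 control window (exact adjusted p = 0.1).

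**Figure D3:**
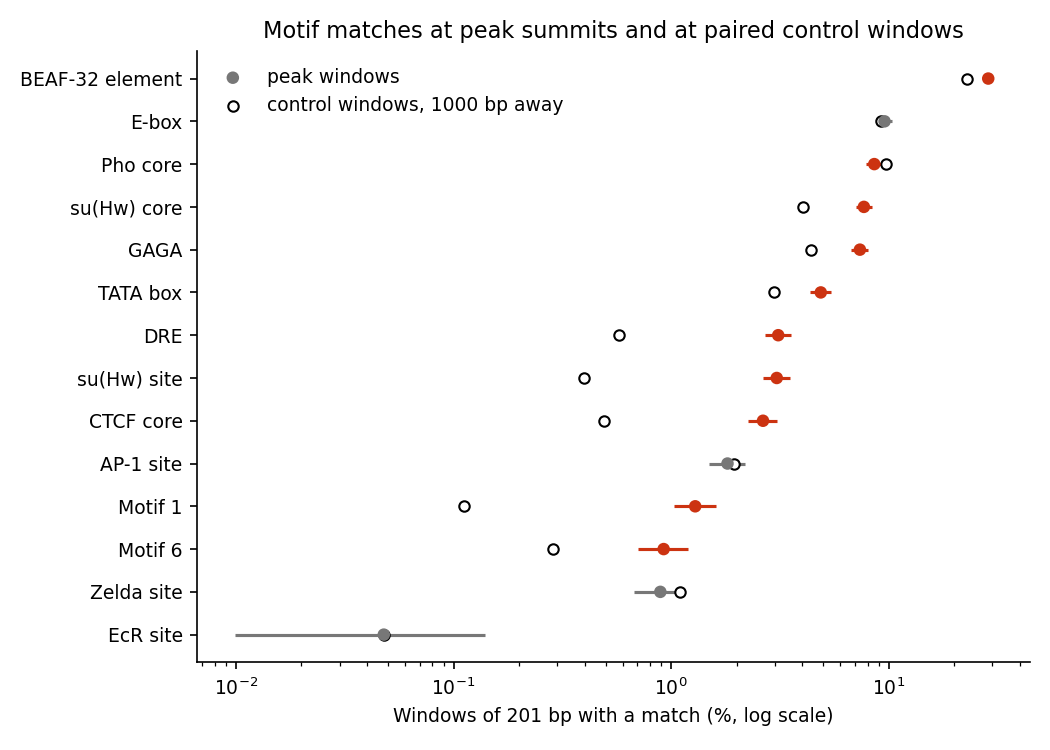
Percentage of windows with a match (x axis, log scale) for each motif, at peak summits (filled points, exact 95% binomial intervals as bars, red where called) and in paired windows 1000 bp away (open circles). The su(Hw) site lies at 3.06% against 0.399% and Motif 1 at 1.29% against 0.112%.

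Promoters with a peak held the DRE, the BEAF-32 element and Motif 1 more often than other promoters, and the TATA box less often. The DRE was found at 11.5% of the 2295 promoters with a peak at their outermost start site and at 7.11% of the 11650 without (two-sided Fisher exact adjusted p = 2.81e-11). The BEAF-32 element gave 48.0% against 37.7% (exact adjusted p = 9.12e-19), the E-box 17.9% against 12.97% (exact adjusted p = 4.23e-09), the GAGA sequence 6.19% against 3.19% (exact adjusted p = 2.92e-10) and Motif 1 5.93% against 3.55% (exact adjusted p = 8.78e-07). Motif 6 (2.83% against 1.44%, exact adjusted p = 2.01e-05) and the CTCF core (0.915% against 0.472%, exact adjusted p = 0.0218) were also more frequent. The TATA box was less frequent, at 4.49% against 8.50% (exact adjusted p = 2.81e-11). The other 6 motifs, the su(Hw) site included (0.349% against 0.249%, exact adjusted p = 0.517), were not called. With windows of 200 bp to each side the su(Hw) site was called above other promoters (exact adjusted p = 0.0013) and the Pho core below (exact adjusted p = 6.18e-05).

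The su(Hw) site was more frequent at distal peaks and the DRE at promoter peaks, in splits made after the data were seen. Of distal peaks, 4.18% had a su(Hw) site, against 1.52% of promoter peaks (two-sided Fisher exact adjusted p = 9.25e-10). The DRE was at 6.60% of promoter peaks and 0.578% of distal peaks (exact adjusted p = 2.55e-43), and Motif 1 at 2.96% and 0.0825% (exact adjusted p = 1.86e-25). With the arm peaks in 4 equal groups by signal, 6.82% of the windows of the strongest group had a su(Hw) site (exact 95% interval 5.62 to 8.18), and 1.15% of those of the weakest group did. The CTCF core was at 4.97% of the strongest and 1.59% of the weakest group. The DRE did not follow signal in this way: from the strongest group to the weakest it was at 3.25%, 4.08%, 3.38% and 1.72%.

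**Figure D4:**
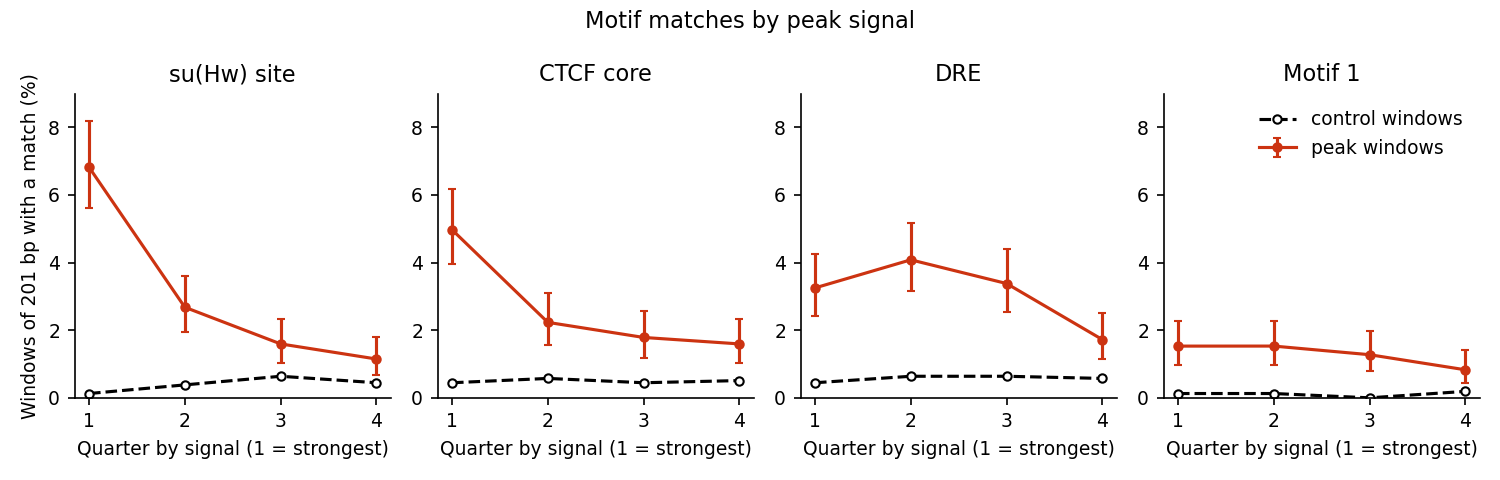
Percentage of windows with a match (y axis) in 4 equal groups of arm peaks by signal (x axis, 1 = strongest) for the su(Hw) site, CTCF core, DRE and Motif 1, with exact 95% binomial intervals at peak windows (red) and paired control windows as open circles. Peak windows with a su(Hw) site go from 6.82% in the strongest group to 1.15% in the weakest.

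Named regions were inspected for peaks. Between yellow (y), a pigmentation gene, and the proneural gene achaete (ac) on X, a region known for the su(Hw)-dependent 1A2 insulator, there was 1 peak (X 361469–361819, signal 958.5). It held place 97 among the arm peaks of the thresholded list and, with mitochondrial peaks counted, places 127 and 106 in the lists of replicates 3 and 4. Its summit lay in an intron of CG32816, 11 bp from a su(Hw) site, TGTTGCATACTC, at 361614–361625.

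The bithorax complex, which holds Ubx, abd-A and Abd-B, the Hox genes of the posterior trunk, had 7 peaks over 315.61 kb (2.22 per 100 kb, against 4.69 over the arms). The strongest (3R 16798443–16798858, signal 336.9) lay between genes, upstream of Ubx and downstream of abd-A. A CTCF core was within 100 bp of 4 of the 7 summits: AGATGGCGC in the intron of bxd, AGGGGGCGC in each of 2 peaks in an intron of MSAmiP (3R 16869184–16869599 and 16882510–16882925), and AGGTGGCGC in an intron of Abd-B (3R 16969530–16969945, 180.8). These 4 peaks were weak, with signals of 146.2, 165.7, 123.9 and 180.8 in that order, in a list that starts at 113.2. Each lay outside the strongest 6294 peaks of 1 replicate. Their places in replicates 3 and 4 were 7646 and 3054, 2698 and 9552, 8056 and 6160, and 8333 and 1230. No summit was within 500 bp of a start site of Ubx, abd-A or Abd-B.

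The Antennapedia complex, from lab to Antp, had 11 peaks over 337.80 kb (3.26 per 100 kb). The strongest, at 749.3 (3R 6912213–6912503), lay in an intron of Antp and of the overlapping CG46458, with 2 CTCF cores, AGGTGGCGC and AGATGGCGC, within 100 bp of the summit and the string GCATACTT, part of the su(Hw) sequence, 12 bp from it. There were 4 further peaks in Antp introns, with signals from 137.1 to 262.4. The only peak near a gene start of the complex's homeobox genes was at bcd, 236 bp from its start (228.1).

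The mod(mdg4) gene itself (3R 21350846–21377401) held no peak in the thresholded or the pooled list. The pooled list, which also holds background, had 66 peaks in the bithorax complex and 85 in the Antennapedia complex. The line carries a tagged mod(mdg4) transgene, and its effect on reads and control coverage at this sequence was not examined. The absence thus does not show that the protein is missing from its own gene. The nearest summits were 927 bp to its left, 318 bp from the start of aus (signal 340.07), and 8934 bp to its right, near bap (339.49). The interval from CG3281 to aurA at the 87A heat shock locus (3R 11960883–11964826) had no peak, but it spans only 3.94 kb on this annotation and holds no Hsp70A gene, so it says little about the scs elements it was chosen for.

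**Figure D5:**
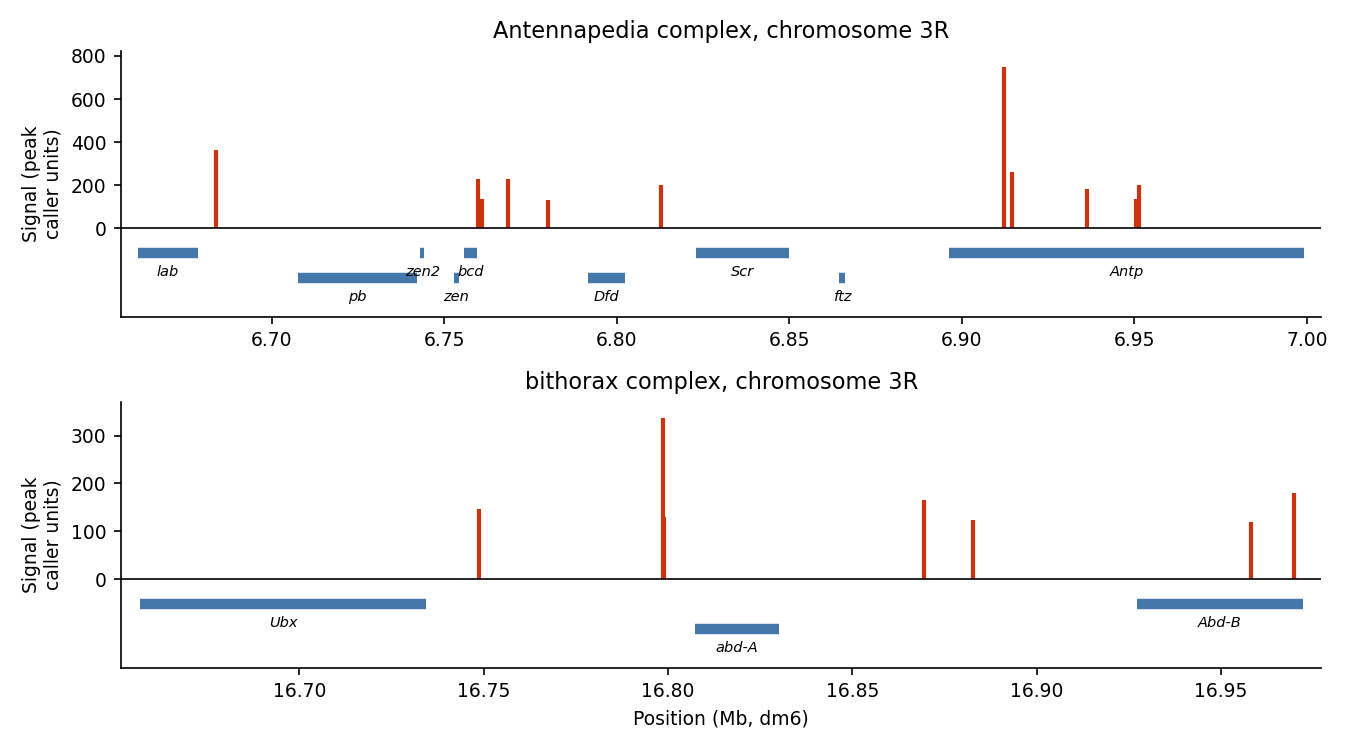
Peaks of the Antennapedia and bithorax complexes on 3R, with position in Mb on the x axis, peak signal in peak caller units as red lines on the y axis, and homeotic complex genes as blue bars. The strongest peak of the Antennapedia complex (749.3) lies within Antp and that of the bithorax complex (336.9) between Ubx and abd-A.

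The X chromosome, which male flies carry in a single dosage-compensated copy, had a share of peaks close to its share of start sites. Of 6206 peaks on the 5 largest arms, 1073 (17.3%, exact 95% interval 16.4 to 18.3) were on X, against 17.1% of protein-coding start sites (two-sided exact binomial p = 0.673). The share was 17.4% in replicate 3 (exact p = 0.533) and 16.1% in replicate 4 (exact p = 0.0363), which put the latter below the reference. Other settings passed the threshold in opposite directions: the share was 17.9% with the strongest 12588 pooled peaks (exact p = 0.0133), above the reference, and on dm3 it was 17.2% against 18.8% of arm length (exact p = 0.0011).

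The same libraries were processed on dm3 and dm6, and their lists are set side by side without converting coordinates. On the arms the builds gave similar lists, with 6190 thresholded peaks on dm3 and 6273 on dm6 and a median signal 1.03 times higher on dm3. This ratio and the mitochondrial signals set 2 lists side by side, each on its own scale. The overlap of the replicates was 73.3% on each. On the mitochondrial genome there were 4 peaks on dm3, the highest at 979.8, and 21 on dm6, the highest at 29357.6 in mt:CoII, which encodes a cytochrome oxidase subunit.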

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

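Both tests in this part were chosen only after the result was seen.

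The mitochondrial genome lies outside the comparisons with genes and motifs, yet it led the dm6 lists. The thresholded list held 21 mitochondrial peaks in 11 intervals, which covered 10108 of 19524 bp (51.8%). The highest, in mt:CoII, had a signal of 29357.6, which was 12.1 times that of the strongest arm peak. Peaks in mt:CoI (18046.1), mt:ND5 (16692.0) and mt:Cyt-b (16251.6) followed, and the weakest lay at 114.6 in the sequence annotated as mt:ori.

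A single aberrant replicate is argued against, because mitochondrial peaks took 19 of the first 20 places in each replicate list. The build mattered: the highest mitochondrial signal on dm3 was 0.0334 times that on dm6, while the median signal of nuclear peaks was 1.03 times higher, so the scales of the lists differed far less than that. This is in line with mitochondrial reads having been assigned or kept differently on the 2 builds, as a step of processing. What remains open is why, and whether mitochondrial DNA was enriched over the control library by precipitation or by its amount in the extracts. No biological explanation was tested, since there is 1 group and the control library was not used here.

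The thresholded dm3 list also held 10 peaks on sequence outside the arms and the mitochondrial genome, namely 3 on 2RHet (highest signal 2444.3), 2 on 3LHet and 5 on Uextra.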

How the results depend on the processing

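The settings restricted to nuclear chromosomes, without histone genes, to peaks strong in both replicates, and to the 25 strongest arm peaks were chosen only after the data were seen. Of 54 alternatives for the main results, 45 kept their direction and side of the threshold or, for counts and values without a test, stayed near the main value; their size could still move. The signal difference between promoter and distal peaks was 14.01 among the stronger 3147 peaks and 37.9 with the strongest 12588, and called lists fell from 6 to 4 with single-start genes only. Rank correlation between replicates moved to 0.732 over all pooled peaks found in both and turned to -0.105 in the weaker 0.5 of the thresholded list, whose narrow band of pooled signal comes from that selection. Called lists rose to 11 with the strongest 12588 pooled peaks, and the genes named from the strongest peaks from 2 to 9 on the arms alone, because mitochondrial peaks then took no place. The X share lay below its reference in place of above it against arm length (17.3% against 17.8%, exact p = 0.336), on dm3 against arm length (17.2% against 18.8%, exact p = 0.0011) and among the stronger 3147 peaks (16.8%, exact p = 0.721), and above it with the strongest 12588 peaks (17.9%, exact p = 0.0133); the cause was not tested. Without either replicate it ranged from 16.1% to 17.4%, the lower from replicate 4 alone (exact p = 0.0363). Over the same leave-outs the promoter share ranged from 43.3% to 45.7%, the signal difference from 7.01 to 14.04, called lists from 6 to 7, called motifs from 10 to 11, and promoter motifs stayed at 8. For single lists, 186 of 199 alternatives gave the same call, 3 lost one (ecdysone response, heat shock, histones) and 10 gained one. Insulator protein genes gained a call at 250 bp, among the stronger 3147 peaks and with peaks strong in both replicates. Proteasome genes, below other genes, gained one at 1000 bp and with the strongest 12588 peaks. Cell cycle genes did so without replicate 4 and with the strongest 12588 peaks. Apoptosis, patterning and testis-specific genes (the last below other genes) did so with the strongest 12588 peaks. Over all alternatives the exact adjusted p of insulator genes ranged from 0.03 to 0.294, that of proteasome genes from 0.0108 to 0.261 and that of cell cycle genes from 0.0125 to 0.456, so none of the 3 is a settled call. For single motifs at peaks, 107 of 112 gave the same call, and at promoters 54 of 56. Depth is unknown, so its effect on weak peaks could not be measured. No paired analysis was possible because there is 1 group.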

Other observations

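The test on base composition, the tighter of 2 matchings of gene lists, and all descriptive counts of genes, k-mers and gaps were chosen only after the data were seen.

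Peaks lay at 109 of 290 transfer RNA genes (37.6%, exact 95% interval 32.0 to 43.4), against 18.7% of protein-coding genes. With tRNA genes within 2 kb of one another counted once, 50 of 159 clusters (31.4%, exact 95% interval 24.3 to 39.3) had a peak at their first gene, an interval above the protein-coding share. Some of these are also promoter peaks of protein-coding genes: with summits over 500 bp from any protein-coding start site only, 88 tRNA genes (30.3%, exact 95% interval 25.1 to 36.0) had a peak. The strongest were at tRNA:Arg-TCG-2-4 (1660.1, 3R 8863134–8863595), a peak that is also 157 bp from a start site of the junction protein gene pyd, at tRNA:Leu-TAG-1-2 (1170.7) and at tRNA:Pro-TGG-1-5, inside an intron of the piRNA pathway gene qin (999.5). Other classes gave 8 of 32 snRNA genes (25%), 22 of 269 snoRNA genes (8.18%), 256 of 2780 genes of other noncoding RNAs (9.21%) and 15 of 268 pseudogenes (5.60%). None of 99 rRNA genes had a peak. As for the histone genes, the treatment of reads that match several copies is not given, so this does not show absence of binding. Apart from the comparison of tRNA clusters with protein-coding genes, these shares were not tested against each other.

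The genes with the most summits inside their span, counted without scaling to gene length, included 3 of the ecdysone response list. Eip75B, an ecdysone-induced nuclear receptor gene, held 26 summits over 113.7 kb, EcR 19 over 81.2 kb and Eip74EF 16 over 60.7 kb. Tet, the gene of a DNA and RNA dioxygenase, held 22, CG1677 19, the kinase gene Tlk 19, bun 17, sbb 17 and shn, a mediator of Dpp signalling, 16. Among the genes with the highest counts, the densest were Tis11, which encodes an RNA-binding protein, at 47.5 summits per 100 kb, tara at 40.4 and Mnt at 40.2. The arms as a whole had 4.69, and genes with fewer summits were not ranked by density. The longest stretches without a summit were on 2R (1243777 to 4728913, 3.49 Mb) and 3L (22982269 to 26012500, 3.03 Mb), on the sides of those arms nearest the centromere.

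The strongest arm peak (2R 1243297–1243958, signal 2429.3) lay between genes, 20594 bp from CG40191, and held 12 su(Hw) sites, such as TATTGCATACTT at 1243503–1243514. The next highest counts were 5 sites in 3L 28091223–28091507 and 3 in 3L 2244071–2244497, beside CG32301. Of 6262 arm intervals, 229 held a site and 7 held more than 1. The insulator of the gypsy retrotransposon is known as a run of su(Hw) sites; whether this interval is a copy of it was not tested. Of 62 words of 50 bp sampled along the interval, 6 (9.68%) were found elsewhere in the assembly.

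Without use of the fixed motifs, the 8-base string most in excess at peaks was AAGTATGC, the complement of GCATACTT, which overlaps the su(Hw) sequence. It was in 6.58% of all arm peak windows against 0.869% of control windows, and in 14.3% against 0.829% for the strongest 1569 peaks. At promoter peaks, TATCGATA, the DRE, led with 6.60% against 0.645%, and GGTCACAC, part of Motif 1, had 5.01% against 0.683%. A su(Hw) site, a CTCF core or the string GCATACTT was found at 9.60% of arm peaks, and a DRE, Motif 1 or Motif 6 at 5.07%. Both kinds were found at 15 peaks (0.239%), and neither at 85.6%. The string GCATACTT is not among the 14 fixed motifs and led the excess at these same peaks, so the 9.60% leans on it. The fixed su(Hw) site and CTCF core were at 3.06% and 2.65%.

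The su(Hw) site was most frequent at the strongest peaks. GC content is argued against, because the windows of the strongest 1569 and the weakest 1568 peaks had nearly the same mean, 37.3% and 37.2%. Weighting the weakest to the GC content of the strongest could therefore change little. The site was then 5.71 times as frequent in the strongest (6.82% against 1.195%, bootstrap 95% interval of the ratio 3.81 to 10.8). Other features of base composition were not covered. Sharper summits at strong peaks are argued against, because in windows of 400 bp to each side, the excess over control was 4.75 times higher in the strongest than in the weakest group (7.27% against 1.53%, bootstrap 95% interval of the ratio 2.78 to 13.99). The strongest group held more promoter peaks than the weakest (48.9% against 34.8%), where the site was rarer, so the promoter share could only have lowered its frequency there; among distal peaks alone the ratio was 6.92 (9.90% against 1.43%, interval 4.12 to 13.3). A hypothesis left open is that su(Hw) may recruit or retain more tagged protein than other sites do, which these data were not designed to test.

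Ecdysone response genes have more start sites and are longer than most genes, with medians of 3 and 21.8 kb against 1 and 2.17 kb, so their promoter peaks could follow from gene structure. Lists of genes matched on both reached the 15 genes with a peak in 1.11% of 10000 draws, with a mean of 9.49, when each gene was drawn from its 20 nearest matches. With the 50 nearest matches, tried first, 0.73% of draws reached it. Structure thus went with part of the excess. Among single-start genes the odds ratio was 1.34 in place of 7.26 and the call ended, over only 6 members (1 with a peak, 16.7%, exact 95% interval 0.421 to 64.1), while with more start sites 14 of 18 members (77.8%, interval 52.4 to 93.6) and 34.5% of other genes had a peak. The lower replicate count was 0.933 times the observed one. Each replicate count came from the strongest 6294 peaks of that replicate alone and was 14 of 24 genes. This argues against a single replicate having carried the count. Of the thresholded peaks, 70.8% overlapped a peak among the strongest 6294 of each replicate. A share of 98.8% overlapped a peak of both full lists, which also hold background.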
